A study of Mus musculus with 20 samples.

How the data were processed

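Kidneys of aged mice with transplanted bone marrow were profiled by RNA sequencing, with 1 library per animal within each table and no library in both tables. Total RNA was extracted with QIAzol and an RNeasy kit and sequenced at Novogene on a NovaSeq X, per the labels' protocols. The authors deposited gene counts, with reads placed on mm10 per the submitters' processing notes; the aligner, counting program, annotation and strand setting are not given in the sources used here. The deposited values were whole numbers in every column, and they were used as counts.

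The LOY table named 26608 genes in 12 kidneys, of which 5629 had no count, and 25 carried symbols that looked like dates. Its entry for reads without a gene held 0.223% to 0.401% of the counts and was left out. It had no mitochondrially encoded genes. The ABT-263 table named 30809 genes in 8 kidneys; 224 had no count, and 24 symbols stood for 190 genes, which were kept apart and not named. Mitochondrially encoded genes took 7.91% to 11.1% of its counts. The tables shared 17350 symbols and were tested apart. Replicates were checked as distinct libraries: the lowest median of squared count differences over genes, relative to its Poisson expectation, was 4.00 over 30 pairs and 3.41 over 12 pairs.

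Groups followed the labels: 6 Control against 6 LOY kidneys, and 4 LOY kidneys with the control compound against 4 with ABT-263. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood F test), with Benjamini-Hochberg adjustment and a threshold of 0.05. Values are log2 fold changes ± SE, the SE being the size of the log2 fold change over the square root of F. CPM are means ± SD with TMM-scaled totals. DESeq2 1.42.0 and voom with sample quality weights in limma 3.58.1 were run beside edgeR.

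A total of 39 gene lists was fixed before the data were examined, as were the comparisons, the tests and the first set of alternatives. Lists with at least 5 tested members went to camera (limma) with a preset correlation of 0.01, adjusted over 36 lists per comparison, and again with a correlation estimated from the data and with fry. Members were also adjusted over their list alone. A list score is the median over members of the log2 CPM deviation in each kidney (prior count 2). Exact two-sided permutation of these scores over all 924 or 70 splits was chosen after the data were seen. Coordinates are from GENCODE M21 (GRCm38), and older and newer symbols were matched through RefSeq.

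Genes were named by rule. Per comparison these were the 6 largest rises and 6 largest falls past the threshold with a mean of at least 1 CPM, or, where none passed, the 4 smallest p in each direction as values. Added to them were focus genes fixed beforehand and up to 3 smallest-p members of each list that passed or held genes past the threshold. Genes from lists added later are said to be so where they appear. Results on a few genes that meet the rule are not reported here.

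The genes that passed with LOY were carried to the ABT-263 table as lists, and differences of mean log2 CPM were correlated over the genes of both tables. Both were set against all 35 splits of the 8 kidneys; the gene and list counts were set against 100 drawn splits of the 12 kidneys and the same 35.

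The scripts were tested on simulated data with 200 changed genes. In the LOY design edgeR recovered 27.3% of 1.5-fold, 71.6% of 2-fold and 95.5% of 4-fold changes, and 3.73% of its calls were unchanged genes. In the ABT-263 design these were 30.3%, 68.2%, 90.6% and 9.56%. Unchanged genes made up 15.0% and 20.7% of DESeq2 calls, and 5.22% and 8.33% of voom calls, in the LOY and ABT-263 designs. The list tests called the 1 raised list and 0 of 35 unchanged ones. Simulated genes varied independently and the lists were random, so false calls among correlated genes were not tested. In the real LOY table the estimated correlation within a list reached 0.82 (ribosomal proteins).

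Alternatives fixed beforehand were other scalings (median-ratio, upper-quartile, totals alone), no filter, a mean of at least 1 CPM, a test of changes over 1.2-fold, an adjusted p of 0.1 and leaving out each kidney. Chosen after seeing the data were animal number as a term, the animals numbered above 10 alone, and leaving out LOY animal 8 with Control animal 3, LOY animals 8 and 10, or control-compound animal 6 with ABT263 animal 16. So were leaving out kidneys in the comparison of the tables and LOY lists from fewer animals. Protein levels, splicing and reads were not analysed here.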

Results

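Gene expression was measured by RNA sequencing of kidneys from aged mice that had received bone marrow transplants. LOY is the loss of the Y chromosome from blood-forming cells, which men acquire with age, and the transplants gave mice with a Control or a LOY blood system. A table of 12 kidneys held 6 Control animals (numbered 3, 11, 12, 13, 16 and 17) and 6 LOY animals (5, 8, 9, 10, 14 and 18). A separate table of 8 kidneys held LOY animals given a control compound (6, 8, 9 and 10, n = 4) or the senolytic ABT-263 (15, 16, 17 and 18, n = 4). ABT-263 (navitoclax) inhibits BCL-2, BCL-XL and BCL-W, and a senolytic is a compound that kills senescent cells. Total gene counts per kidney lay between 13332563 (Control animal 16) and 19386408 (LOY animal 18) in the LOY table, and between 14587809 (ABT263 animal 18) and 20791633 (control-compound animal 8) in the ABT-263 table.

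The LOY and Control kidneys were compared to see what a LOY blood system changes in the kidney; the series title names immune checkpoints, senescent cells and renal disease. Macrophage, antigen presentation, T cell and tubular injury transcripts were higher in LOY kidneys, and transcripts of the proximal tubule and of fatty acid oxidation were lower. Of these lists only the T cell list also passed with an estimated correlation between genes (adjusted p = 0.0308; the others 0.166 to 0.331). Beside LOY, the proximal tubule and fatty acid oxidation lists also followed animal number, being higher above number 10 (median 0.25 each). Their camera adjusted p with number was 0.00178 and 0.000640 (0.605 and 0.581 with an estimated correlation). The macrophage and tubular injury lists were lower above number 10 (median -0.23 and -0.35). Of 14978 tested genes, 167 rose and 9 fell. Lyz2, the lysozyme of macrophages, rose from 71.1 ± 11.8 to 165 ± 37.1 CPM (counts scaled to library size; SD, n = 6 per group). Havcr1, which encodes the tubular injury marker KIM-1, rose from 32.1 ± 22.7 to 94.6 ± 26.5 CPM, and Lcn2, encoding the injury marker NGAL, rose from 24.6 ± 15.7 to 108 ± 71.2 CPM.

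Among 34 macrophage and monocyte genes 15 rose and 0 fell over all genes tested, and 30 rose when adjusted over the list alone. Their median log2 fold change was 0.97 (camera adjusted p = 3.10e-22; adjusted p = 0.166 with an estimated correlation). Lyz2 (chromosome 10, 117277331 to 117282321, GRCm38) had a log2 fold change of 1.21 ± 0.15 (SE) and an edgeR adjusted p of 0.0146. The lysosomal protease Ctss (1.11 ± 0.15, adjusted p = 0.0146), the Fc receptor Fcgr3 (1.14 ± 0.17, adjusted p = 0.0166) and the complement subunit C1qc (1.05 ± 0.18, adjusted p = 0.0250) rose as well. The score of the list, its median log2 deviation in each kidney, averaged -0.460 ± 0.273 in Control and 0.469 ± 0.251 in LOY kidneys (SD, n = 6 each). It was higher in 6 of 6 LOY kidneys than in every Control kidney (exact two-sided permutation p = 0.00216, the smallest that 924 splits can give).

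Of 43 genes of antigen presentation and the interferon gamma response, 12 rose and 29 rose when adjusted over the list alone (median 0.62, camera adjusted p = 7.88e-16; adjusted p = 0.166 with an estimated correlation). The MHC class II genes led, with H2-Aa at 0.96 ± 0.14 (153 ± 30.7 to 299 ± 45.1 CPM), H2-Eb1 at 0.91 ± 0.15 and H2-Ab1 at 0.79 ± 0.14. All 26 tested T and natural killer cell genes had positive changes, 5 of them past the threshold and 22 when adjusted over the list alone (median 1.24, camera adjusted p = 4.57e-15). This was the only list of 36 that also passed with an estimated correlation (adjusted p = 0.0308). Its smallest p belonged to the chemokine Ccl5 (1.30 ± 0.26), the T cell kinase Zap70 (1.44 ± 0.30) and the T cell receptor chain Cd3g (1.62 ± 0.36). Of 37 type I interferon response genes 3 rose, Irf9 (0.55), Pyhin1 (0.94) and Mx1 (1.03), and 20 rose when adjusted over the list alone (median 0.56, camera adjusted p = 3.56e-11; adjusted p = 0.166 with an estimated correlation).

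**Figure D1:**
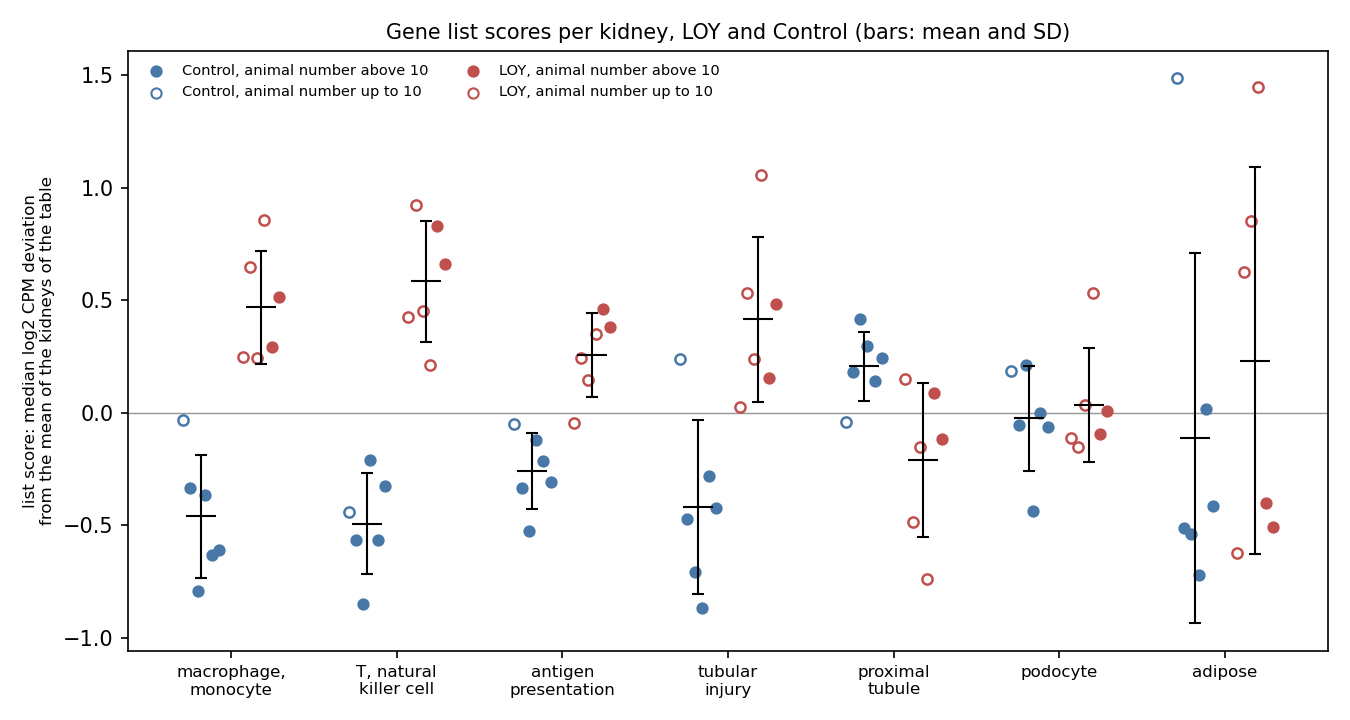
List scores of 7 gene lists in each LOY and Control kidney (6 animals per group; bars, mean and SD), with open points for animals numbered up to 10. All 6 LOY kidneys lie above all Control kidneys for the macrophage list (mean 0.469 against -0.460), while podocyte and adipose scores overlap. Tubular injury and proximal tubule scores overlap too. For injury 4 LOY kidneys lie above all Control kidneys, and for the proximal tubule 4 lie below all of them.

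Tubular injury genes rose as a group: 9 of 34 passed, 28 when adjusted over the list alone, and 33 had positive changes (median 0.83, camera adjusted p = 2.39e-13; adjusted p = 0.166 with an estimated correlation). Cd44, a hyaluronan receptor of injured tubules, rose by 1.33 ± 0.21, the adhesion molecule Vcam1 by 1.30 ± 0.22 and the macrophage growth factor Il34 by 0.83 ± 0.16. Havcr1 (chromosome 11, 46735080 to 46779578) changed by 1.56 ± 0.33 (adjusted p = 0.0378) and Lcn2 (chromosome 2, 32384633 to 32388252) by 2.14 ± 0.45 (adjusted p = 0.0386). The 6 largest rises among genes with a mean of at least 1 CPM were Mmp7 (2.82 ± 0.45), Il1f6 (2.66 ± 0.58), Krt20 (2.49 ± 0.56), Ccl8 (2.23 ± 0.45), Lcn2 and Cxcl1 (2.12 ± 0.48). Mmp7 (chromosome 9, 7692090 to 7699585) encodes a matrix protease and went from 0.455 ± 0.301 to 3.29 ± 1.41 CPM. Markers of the urothelium, which lines the renal pelvis, were also higher (12 of 13 positive, median 0.76, camera adjusted p = 0.00245; adjusted p = 0.399 with an estimated correlation), with 0 members past the threshold and 2 when adjusted over the list alone. Their score differed by 0.770 (exact permutation p = 0.139), by 0.494 among the animals numbered above 10 (exact permutation p = 0.619) and by 0.352 without LOY animals 8 and 10 (exact permutation p = 0.486).

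Secreted factors associated with senescence included 11 of 50 genes that rose; adjusted over the list alone 22 rose and 2 fell (median 0.64, camera adjusted p = 7.81e-09; adjusted p = 0.166 with an estimated correlation). Cxcl16 (0.79 ± 0.14), the macrophage growth factor Csf1 (0.91 ± 0.16) and Icam1 (0.80 ± 0.16) had the smallest p. Extracellular matrix and fibrosis genes were higher in 47 of 50 cases, 2 past the threshold, Mmp14 (1.10 ± 0.22) and Vim (1.03 ± 0.24), and 22 when adjusted over the list alone (median 0.45, camera adjusted p = 2.11e-11; adjusted p = 0.185 with an estimated correlation). The collagen gene Col1a1 changed by 1.05 ± 0.25 (50.3 ± 20.6 to 104 ± 36.0 CPM) and missed the threshold (adjusted p = 0.0508). Complement genes included 3 of 21 that rose, C3 (1.21 ± 0.24), Cfp (0.99 ± 0.22) and C1s (0.54 ± 0.12), and 9 when adjusted over the list alone (median 0.51, camera adjusted p = 6.69e-05; adjusted p = 0.166 with an estimated correlation).

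Cell cycle genes were higher in 32 of 35 cases, with Plk1 (1.17 ± 0.20) and Birc5 (1.49 ± 0.33) past the threshold and 11 when adjusted over the list alone (median 0.48, camera adjusted p = 4.90e-08; adjusted p = 0.166 with an estimated correlation). Immediate early genes included 3 of 21 that rose, Atf3 (1.62 ± 0.35), Klf6 (0.79 ± 0.17) and Jun (0.82 ± 0.19), and 13 when adjusted over the list alone (median 0.68, camera adjusted p = 4.90e-08; adjusted p = 0.166 with an estimated correlation). Of 29 heat shock and unfolded protein response genes the small chaperone Hspb1 rose (1.52 ± 0.34), and 7 rose when adjusted over the list alone (median 0.33, camera adjusted p = 0.00162, and adjusted p = 0.288 with an estimated correlation). Their score differed by 0.251 over all kidneys, by 0.153 among the animals numbered above 10 (exact permutation p = 0.0952) and by 0.301 without LOY animals 8 and 10 (exact permutation p = 0.0286). Among 28 efferocytosis genes 5 rose, among them C1qc, the GTPase Rac2 (1.18 ± 0.22) and the receptor tyrosine kinase Axl (0.54 ± 0.10), and 6 when adjusted over the list alone (median 0.18, camera adjusted p = 0.00372; adjusted p = 0.249 with an estimated correlation).

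The 6 largest falls began with Irs2, an insulin signalling adaptor (-1.16 ± 0.21, 13.9 ± 3.06 to 6.18 ± 1.92 CPM) and the potassium channel Kcnt1 (-1.12 ± 0.16, 52.8 ± 13.7 to 24.3 ± 1.51 CPM). With them fell the urate and phosphate transporter Slc17a4 (-0.82 ± 0.17), Adck3 (-0.73 ± 0.16), the vitamin transporter Slc5a6 (-0.68 ± 0.15) and Dixdc1 (-0.60 ± 0.14). Irs2 lies on chromosome 8 at 10984681 to 11008458. Proximal tubule genes were lower in 39 of 46 cases (median -0.37, camera adjusted p = 2.47e-08; adjusted p = 0.241 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. Their smallest p belonged to the lactate transporter Slc5a12 (-1.17 ± 0.29, adjusted p = 0.0636), the amino acid transporter Slc6a19 (-1.64 ± 0.45, adjusted p = 0.0860) and the endocytic receptor Cubn (-0.54 ± 0.17, adjusted p = 0.122). The proximal tubule score differed by -0.415 over all kidneys, by -0.270 among the animals numbered above 10 and by -0.213 without LOY animals 8 and 10 (exact permutation p = 0.0667). Fatty acid oxidation genes were lower in 31 of 33 cases (median -0.24, camera adjusted p = 1.83e-05; adjusted p = 0.331 with an estimated correlation), again with 0 members past either threshold. Their score differed by -0.267 over all kidneys, but by -0.0890 among the animals numbered above 10 (exact permutation p = 0.190 of 21 splits) and by -0.111 without LOY animals 8 and 10 (exact permutation p = 0.0667). Distal tubule and collecting duct genes had a median of -0.17 (camera adjusted p = 0.0462; adjusted p = 0.166 with an estimated correlation), and this call was lost in 12 of 20 other settings. Their score differed by -0.141 over all kidneys, with 6 of 6 LOY kidneys below every Control kidney (exact permutation p = 0.00216, adjusted p = 0.0118 over 38 lists). It differed by -0.0653 among the animals numbered above 10 (exact permutation p = 0.0952) and by -0.0960 without LOY animals 8 and 10 (exact permutation p = 0.00476).

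Immune checkpoint genes were higher in 25 of 28 cases; 3 rose, and adjusted over the list alone 9 rose and 1 fell (median 0.39, camera adjusted p = 1.83e-05; adjusted p = 0.166 with an estimated correlation). The members that rose were Lilrb3 (1.14 ± 0.21) and Lilrb4 (0.92 ± 0.18), inhibitory receptors of myeloid cells, and the galectin Lgals3 (1.22 ± 0.28). Cd274, encoding PD-L1, had a log2 fold change of 0.11 ± 0.22 (adjusted p = 0.771). Pdcd1, encoding PD-1, lay below the count filter with 56 counts summed over the Control and 81 over the LOY kidneys. Senescence regulators and markers were higher in 14 of 19 cases with 0 past the threshold and 7 when adjusted over the list alone (median 0.36, camera adjusted p = 0.00507; adjusted p = 0.214 with an estimated correlation). Cdkn1a, encoding p21, changed by 0.52 ± 0.14 (40.3 ± 8.30 to 57.8 ± 8.25 CPM, adjusted p = 0.0702) and Gdf15 by 0.93 ± 0.26 (adjusted p = 0.0911). Cdkn2a, the p16 locus, was also below the filter, with 1 to 9 counts per Control kidney (29 in all) and 5 to 55 per LOY kidney (105 in all). The 34 p53 targets had a median of 0.23, 0 past the threshold and, adjusted over the list alone, 8 higher and 1 lower (camera adjusted p = 0.00700; adjusted p = 0.166 with an estimated correlation). Tgfb1 (0.54 ± 0.14, adjusted p = 0.0673), Fn1 (0.57 ± 0.19, adjusted p = 0.135) and Acta2 (0.59 ± 0.25, adjusted p = 0.188) did not pass.

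Of the 20 BCL-2 family genes, Bcl2a1b (1.62 ± 0.34), which has near-identical copies among which reads can be split, and Bak1 (0.57 ± 0.12) rose. Adjusted over the list alone 4 rose (median 0.25, camera adjusted p = 0.0385, and adjusted p = 0.178 with an estimated correlation). The camera call was lost in 8 of 20 other settings. The ABT-263 targets Bcl2 (-0.04 ± 0.10, adjusted p = 0.846) and Bcl2l1 (0.29 ± 0.13, adjusted p = 0.214) did not pass. The Y-linked genes Ddx3y (-0.18 ± 0.12, adjusted p = 0.378), Uty (-0.21 ± 0.16, adjusted p = 0.432), Kdm5d (-0.36 ± 0.17, adjusted p = 0.232) and Eif2s3y (0.00 ± 0.11, adjusted p = 0.987) did not differ past the threshold. These 4 are expressed widely, so kidney cells contribute to their counts. Their list was too short for camera, and its score was lower by -0.243 in LOY kidneys (exact permutation p = 0.0433, adjusted p = 0.0715 over 38 lists). This difference was -0.124 among the animals numbered above 10 (exact permutation p = 0.190) and -0.134 without LOY animals 8 and 10 (exact permutation p = 0.124).

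Among the other cell types, B and plasma cell genes were higher in 13 of 15 cases with 0 past either threshold (median 0.83, camera adjusted p = 0.00221; adjusted p = 0.249 with an estimated correlation). The tertiary lymphoid structure list had a median of 0.81 over 12 genes, of which Cxcl13 rose (1.62 ± 0.32), and 3 when adjusted over the list alone (camera adjusted p = 0.00330; adjusted p = 0.166 with an estimated correlation). The 5 neutrophil genes had a median of 0.78 (camera adjusted p = 0.00931, and adjusted p = 0.185 with an estimated correlation). Of them Lcn2, which is also a member of the tubular injury list, passed the threshold, and 2 passed when adjusted over the list alone. Smooth muscle genes (median 0.33, camera adjusted p = 0.0417; adjusted p = 0.411 with an estimated correlation) and ribosomal protein genes (74 of 76 positive, median 0.54, camera adjusted p = 4.26e-12; adjusted p = 0.368 with an estimated correlation) were higher with 0 members past either threshold. Among the animals numbered above 10 the ribosomal score differed by 0.0611 (0.428 over all kidneys) and the smooth muscle score by 0.0642 (0.268 over all). The smooth muscle call was lost in 11 of 20 other settings and the ribosomal call in 2 of 20. The oxidative phosphorylation list was higher by its median (0.28, camera adjusted p = 0.0322; adjusted p = 0.748 with an estimated correlation), although its members of smallest p were lower, such as Ndufs1 (-0.41 ± 0.14) and Sdha (-0.48 ± 0.17). With animal number as a term, and in the animals numbered above 10 alone, this list turned to lower.

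The platelet list (adjusted p = 0.243) did not pass, while its member Pf4, a platelet chemokine, rose (1.45 ± 0.32; 1 when adjusted over the list alone). Camera adjusted p was 0.0773 for androgen-dependent genes, 0.0853 for erythroid genes, 0.212 for the loop of Henle, 0.254 for clock genes and 0.321 for the adrenal cortex. It was 0.424 for endothelium, 0.438 for adipose tissue and 0.489 for cholesterol synthesis. It was 0.753 for podocytes, whose median (-0.03) and test were negative and whose mean was 0.03. In these 9 lists 0 members passed when adjusted over the list alone. The mitochondrially encoded and skeletal muscle lists had fewer than 5 tested members.

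In all, 176 genes passed the edgeR quasi-likelihood test at an adjusted p of 0.05 (3418 at an unadjusted p under 0.05), and 26 of 36 lists passed camera, 23 higher and 3 lower. The scores of 21 of 38 lists passed exact permutation adjusted over the lists, a test that takes no account of animal number. For 125 of the 176 genes the 6 LOY values lay wholly above or below the 6 Control values; 302 of all tested genes (2.02%) did so, against 0.216% by chance. The gene count rested on single kidneys: it was 607 without Control animal 3, 3 without Control animal 11, 2 without Control animal 12 and 9 without Control animal 13. It was 96 without LOY animal 9, 1 without LOY animal 10, 116 without LOY animal 14 and 296 without LOY animal 18. It was 0 without Control animal 16 (edgeR, 2870 at an unadjusted p under 0.05) and 0 without Control animal 17 (2611). It was also 0 in edgeR with animal number above 10 as a term (1194 at an unadjusted p under 0.05), where all 167 raised genes kept a positive change and an unadjusted p under 0.05. These genes were chosen by their LOY difference in the same kidneys, so keeping it is not separate evidence. In that fit number itself called 623 genes. The median log2 fold change of the raised genes was 1.06 without and 0.91 with the term (median SE 0.21 and 0.22), and the smallest adjusted p with it was 0.0505.

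The ABT-263 comparison asks whether a senolytic moves kidney expression in mice with a LOY blood system. No single gene passed in edgeR (42 in DESeq2 and 11 in voom), and the 6 groups with the lowest camera p were ribosomal protein, immediate early, heat shock, oxidative phosphorylation, macrophage and B and plasma cell genes, all lower with ABT-263. Only the B and plasma cell list also passed with an estimated correlation (adjusted p = 0.0288; the others 0.579 to 0.641). Immunoglobulin kappa (Igkc) stood at 234 ± 52.1 CPM with the control compound and 65.3 ± 20.7 CPM with ABT-263 (SD, n = 4 each). The germinal centre repressor Bcl6 stood at 85.7 ± 29.1 CPM with ABT-263, a log2 fold change of 2.03 ± 0.25 (SE).

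Of 16956 genes, 0 passed the edgeR test at an adjusted p of 0.05, with 1002 at an unadjusted p under 0.05 (500 higher, 502 lower) and a smallest adjusted p of 0.265. DESeq2 called 42 genes (15 higher, 27 lower) and voom with sample weights 11 (3 higher, 8 lower). The genes of smallest p with higher values were Bcl6 (2.03 ± 0.25, adjusted p = 0.265; chromosome 16, 23965052 to 23988852), Herc3 (0.45 ± 0.08, adjusted p = 0.327), Wdr6 (0.46 ± 0.09, adjusted p = 0.505) and the proteoglycan Vcan (1.67 ± 0.33, adjusted p = 0.536). Those with lower values were Igkc (-1.84 ± 0.24, adjusted p = 0.265; chromosome 6, 70726435 to 70726966), Ighg2c (-3.24 ± 0.52, adjusted p = 0.327), whose reads can be split with other immunoglobulin genes, the matricellular gene Ccn1 (-1.03 ± 0.17) and the stress kinase Map3k5 (-0.41 ± 0.07). DESeq2 gave adjusted p below 0.05 for each of these 8.

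B and plasma cell genes were lower in 18 of 23 cases (median -0.56, camera adjusted p = 8.95e-09; adjusted p = 0.0288 with an estimated correlation; fry adjusted p = 0.0113). Over all genes 0 passed, and 6 were lower when adjusted over the list alone. Beside Igkc and Ighg2c, the B cell receptor component Cd79a had -1.63 ± 0.35 (adjusted p = 0.536). All 4 ABT-263 kidneys scored below all 4 control-compound kidneys on this list (difference -0.708, exact permutation p = 0.0286, the smallest that 70 splits can give; adjusted p = 0.633 over the lists). Leaving out any kidney other than control-compound animal 6 ended the call with an estimated correlation, with adjusted p from 0.0450 to 0.184 over the 8 kidneys. Immediate early genes were lower in 23 of 23 cases (median -0.60, camera adjusted p = 2.18e-09; adjusted p = 0.641 with an estimated correlation), 4 of them when adjusted over the list alone. Ier3 stood at -1.01 ± 0.17 and Klf4 at -0.66 ± 0.17. Heat shock genes were lower in 25 of 29 cases (median -0.28, camera adjusted p = 3.98e-09; adjusted p = 0.579 with an estimated correlation), also 4 when adjusted over the list alone. Atf4 stood at -0.44 ± 0.10, Dnajb1 at -0.53 ± 0.15 and Hspb1 at -0.52 ± 0.15.

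Macrophage genes were lower in 28 of 35 cases (median -0.37, camera adjusted p = 7.63e-09; adjusted p = 0.641 with an estimated correlation), with Lyz2 at -0.84 ± 0.19, C1qc at -0.53 ± 0.16 and Ctss at -0.46 ± 0.14. T and natural killer cell genes were lower in 26 of 29 cases (median -0.45, camera adjusted p = 0.000208; adjusted p = 0.641 with an estimated correlation), with the T cell receptor gene Trbc2 at -0.98 ± 0.30 and Cd4 at -0.86 ± 0.29. In both lists 0 members passed when adjusted over the list alone. Ribosomal protein genes (75 of 77 lower, median -0.14, camera adjusted p = 2.12e-09) and oxidative phosphorylation genes (67 of 73 lower, median -0.10, camera adjusted p = 3.98e-09) had small changes, each with an adjusted p of 0.641 with an estimated correlation.

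Also lower by camera were podocyte (median -0.19, adjusted p = 0.000664), p53 target (-0.08, adjusted p = 0.0120; Pmaip1 -0.65, Mdm2 -0.33), secreted factor (-0.15, adjusted p = 0.0275) and complement genes (-0.15, adjusted p = 0.0448). With an estimated correlation each of these 4 had an adjusted p of 0.641. Tubular injury (median -0.11, mean 0.18, camera adjusted p = 0.0111, lower) and fatty acid oxidation genes (-0.07, adjusted p = 0.0448) had an adjusted p of 0.650 with an estimated correlation. Higher were cholesterol synthesis (17 of 22 positive, median 0.17, adjusted p = 0.00247; Stard4 0.34, Dhcr7 0.30) and urothelium genes (0.32, adjusted p = 0.0354), both with an adjusted p of 0.641 with an estimated correlation. Endothelium (0.15, adjusted p = 0.0109; Ptprb 0.35) and adipose tissue genes (1.29, adjusted p = 0.0297; Pparg 0.94) were higher too, each with an adjusted p of 0.650 with an estimated correlation. Adjusted over the list alone, 2 tubular injury genes and 1 p53 target were lower, and 0 members passed in the other lists of this paragraph. The fatty acid oxidation call was lost in 8 of 13 other settings and turned to higher in 1, and the urothelium call was lost in 7. Calls were lost in 6 settings for tubular injury, secreted factors and complement, in 5 for p53 targets, endothelium and adipose tissue, and in 2 for podocytes and cholesterol synthesis.

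**Figure D2:**
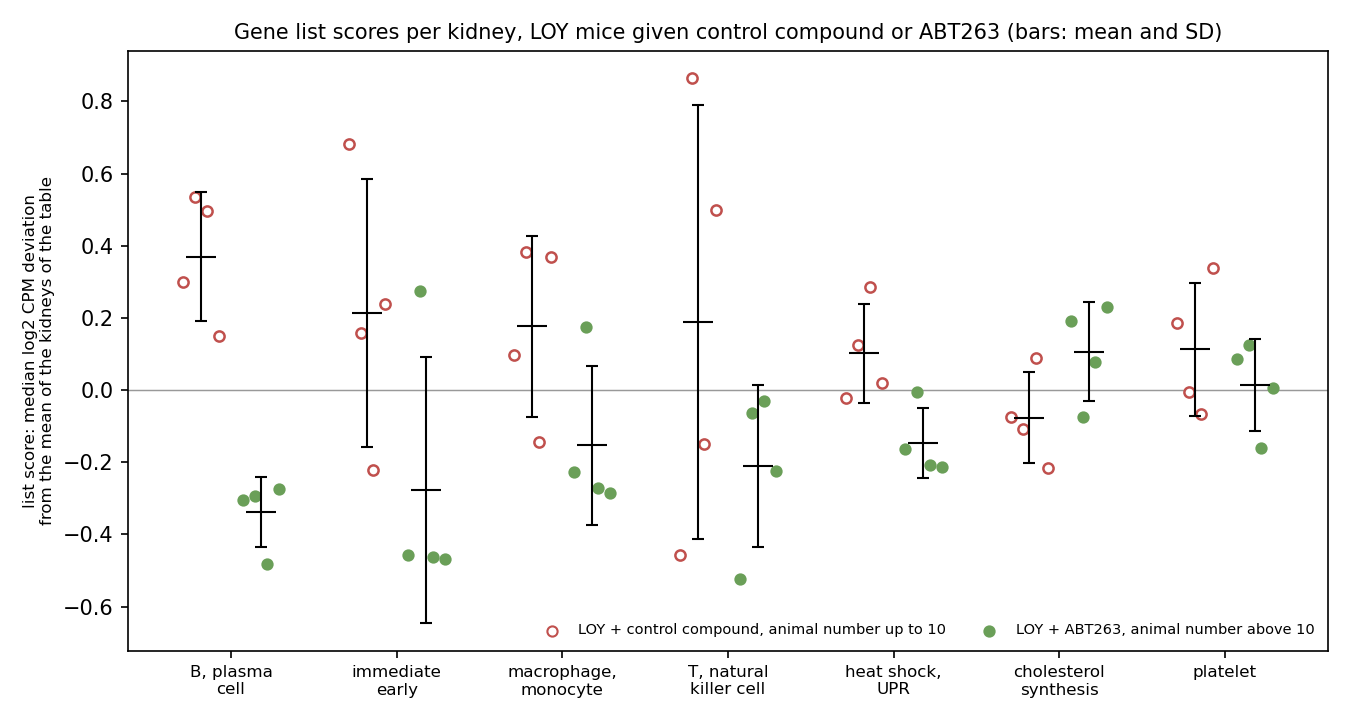
List scores of 7 gene lists in each LOY kidney given the control compound (open points, numbered up to 10) or ABT-263 (filled points, numbered above 10; 4 animals per group; bars, mean and SD). The groups do not overlap for the B and plasma cell list (mean 0.370 against -0.338), and overlap for the others.

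The lists that did not pass camera were distal tubule (adjusted p = 0.0536), type I interferon (0.0594), immune checkpoints (0.0726), efferocytosis (0.0895), neutrophil (0.176), antigen presentation (0.209) and senescence (0.229) genes. The others were loop of Henle (0.229), erythroid (0.231), tertiary lymphoid (0.236), extracellular matrix (0.238), BCL-2 family (0.248), clock (0.264), mitochondrially encoded (0.438), androgen-dependent (0.492), smooth muscle (0.867) and proximal tubule genes (0.972). Extracellular matrix genes had a median of 0.00 and a mean of -0.003. Cell cycle genes (0.492; median 0.08, mean -0.03, lower by the test) and platelet genes (0.955; median 0.06, mean -0.05, lower by camera and higher by fry) differed in sign between measures. Adjusted over the list alone, 1 neutrophil, 1 BCL-2 family, 1 clock, 1 mitochondrially encoded and 1 smooth muscle gene were lower, 1 tertiary lymphoid gene was higher, 1 extracellular matrix gene was higher and 2 were lower. The Y-linked, adrenal cortex and skeletal muscle lists had fewer than 5 tested members.

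Cdkn1a stood at 108 ± 9.63 CPM with the control compound and 93.9 ± 14.9 CPM with ABT-263 (-0.20 ± 0.12, adjusted p = 0.847). Cdkn2a had 16 and 19 counts in all, and Pdcd1 48 and 27, both below the filter. Havcr1 (1.39 ± 1.16, adjusted p = 0.877) and Lcn2 (1.12 ± 1.05, adjusted p = 0.893) were set by ABT263 animal 16, with 12723 counts of Havcr1 and 4393 of Lcn2 (lowest ABT-263 kidney 543 and 273). Col1a1 (0.28 ± 0.53, adjusted p = 0.960), Fn1 (-0.17 ± 0.27, adjusted p = 0.943), Acta2 (-0.45 ± 0.11, adjusted p = 0.657), Tgfb1 (-0.04 ± 0.18, adjusted p = 0.988) and Cd274 (0.08 ± 0.21, adjusted p = 0.971) did not pass. Neither did Bcl2 (0.14 ± 0.11, adjusted p = 0.863) or Bcl2l1 (-0.06 ± 0.12, adjusted p = 0.961). The Y-linked genes had no change past the threshold: Ddx3y (-0.31 ± 0.15, adjusted p = 0.827), Uty (0.10 ± 0.11, adjusted p = 0.910), Kdm5d (-0.10 ± 0.11, adjusted p = 0.912) and Eif2s3y (-0.02 ± 0.12, adjusted p = 0.994).

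Leaving out single kidneys gave 9 genes without control-compound animal 6, 3 without ABT263 animal 16, 1 without ABT263 animal 18. In edgeR 0 passed without each of the others (851, 938 and 897 at an unadjusted p under 0.05 without control-compound animals 8, 9 and 10, and 676 and 689 without ABT263 animals 15 and 17). Without both control-compound animal 6 and ABT263 animal 16 the count was 388 (213 higher, 175 lower). All 4 ABT-263 animals carried numbers above 10 and all 4 control-compound animals numbers up to 10, so the compound and the number cannot be told apart. In the LOY table that division of numbers, which partly follows LOY there, called 4150 genes by itself.

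Genes that rose with LOY were mostly lower with ABT-263 than with the control compound. Of the 167 genes, 155 were tested in the ABT-263 table, and 127 of them (81.9%) had a negative log2 fold change, with a median of -0.28 and 0 genes past the threshold. Lyz2, C1qc, Ctss and Ccl8 (-0.80 ± 0.30) were among them. Camera gave p = 1.60e-16, and p = 0.146 with an estimated correlation; fry gave p = 0.192. Of the 9 genes that fell with LOY, 8 were tested and 7 had positive changes (median 0.28, camera p = 0.0106; p = 0.0707 with an estimated correlation; fry p = 0.120). Without control-compound animal 9 the camera p of these 8 was 0.105, and without ABT263 animal 17 it was 0.0752. Both comparisons run along animal number in opposite directions, so an effect of number would give the same opposite signs. The genes higher with LOY among the animals numbered above 10 alone (327 tested) were also lower with ABT-263, with a median log2 difference of -0.18. Whether animals of the same number in the 2 tables are the same mouse is not given in the sources used here.

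Across 12866 genes measured in both tables, the log2 differences had a Pearson r of -0.286 and a Spearman rho of -0.275. Genes are not independent replicates, and 5 of the 35 splits of the 8 kidneys gave an r as large in size, a share of 0.143. Over the 163 genes called with LOY r was -0.519, and 3 of 35 splits reached that size. Over the 12866 genes with single kidneys left out, each r was set against splits of the kidneys left. From 1 of 35 (without ABT263 animal 16, r = -0.350) to 10 of 35 splits (without control-compound animal 8 or 10, r = -0.239 and -0.201) reached the size of the r given. The opposite courses of animal number apply here as well.

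**Figure D3:**
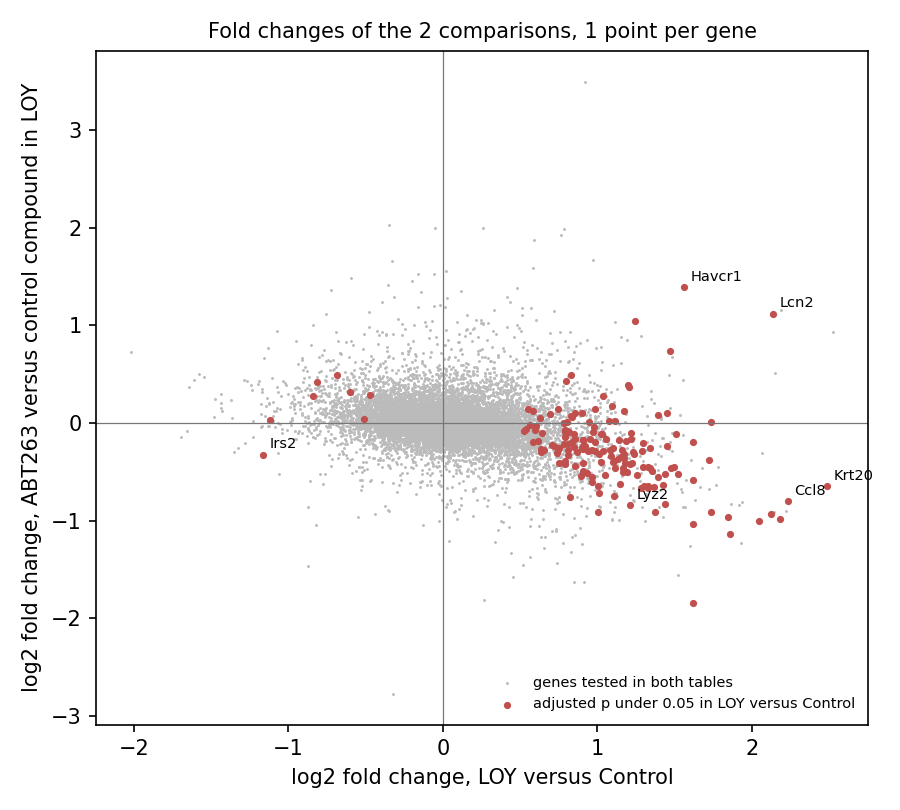
Log2 fold change with LOY (horizontal) against log2 fold change with ABT-263 (vertical) for the genes tested in both tables, with the genes called in the LOY comparison marked. Most genes called higher with LOY lie below 0 on the vertical axis (127 of 155), although none passed the ABT-263 test and 5 of 35 splits gave a correlation as large.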

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

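The tests of animal number, of a structure by animal number, of the tubule share, of LOY animals 8 and 10, of transcript length, of leukocytes falling alike and of other splits, also by number, were chosen only after the result was seen; those of GC content, abundant genes and 1 kidney alone were written before their values.

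Single kidneys stood far from the rest of their group in 29 of 368 groups of values tested (7.88%), where chance gives about 1 in 20; the range of the other kidneys follows in parentheses. The 10 most abundant genes took 12.7% of the counts in LOY animal 8 (7.47 to 9.18) and 14.0% in control-compound animal 6 (11.0 to 11.5). LOY animal 10 had high list scores for senescence regulators, 0.482 (0.00584 to 0.170), secreted factors, 0.728 (0.108 to 0.302), extracellular matrix, 0.632 (0.0826 to 0.267), and podocytes, 0.533 (-0.152 to 0.0364). This kidney, without which the LOY gene count was 1, also held 58 counts of Xist (0 to 9 in every other kidney), the RNA of the inactive X chromosome, whose source was not tested. Control animal 3 had high scores for oxidative phosphorylation, 0.142 (-0.179 to -0.0986), ribosomal proteins, 0.159 (-0.332 to -0.213), and adipose tissue, 1.49 (-0.720 to 0.0183), and a low clock score, -0.566 (0.000703 to 0.236). LOY animal 8 had a BCL-2 family score of 0.519 (-0.0192 to 0.158), and control-compound animal 6 a p53 score of 0.241 (-0.0376 to 0.00719). ABT263 animal 16 had high scores for macrophages, 0.174 (-0.286 to -0.228), and immediate early genes, 0.276 (-0.467 to -0.457), and ABT263 animal 17 a low B and plasma cell score, -0.481 (-0.303 to -0.274).

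Among single genes, in log2 CPM, LOY animal 8 stood apart for H2-Eb1 at 8.76 (8.09 to 8.27), Ddx3y at 5.25 (5.81 to 6.07) and Bcl2l1 at 7.72 (6.85 to 7.11). LOY animal 5 had Mx1 at 1.96 (2.67 to 2.93), and Control animal 3 had Acta2 at 6.54 (5.28 to 5.57). Control-compound animal 9 had Herc3 at 6.29 (6.51 to 6.54) and Ccn1 at 6.44 (6.14 to 6.15). Control-compound animal 6 had Dnajb1 at 5.18 (5.79 to 5.91), Fn1 at 5.92 (7.01 to 7.23) and Ddx3y at 7.01 (6.34 to 6.36). ABT263 animal 16 had C1qc at 5.30 (4.83 to 4.89), Lcn2 at 7.99 (4.21 to 4.24) and Ptprb at 6.15 (6.82 to 6.87), and ABT263 animal 18 had Dnajb1 at 5.02 (5.23 to 5.26).

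The macrophage, antigen presentation and injury lists were higher in LOY kidneys, but 4 of 6 LOY and 1 of 6 Control animals had numbers up to 10. Among animals numbered above 10 the macrophage score still differed by 0.951 (2 LOY, lowest 0.295, and 5 Control, highest -0.333). The size of this difference argued against number as the only cause for that list, though on 2 LOY kidneys. All 6 LOY kidneys already lay above every Control kidney on this score. The exact permutation p of 0.0476 was therefore bound to be the smallest that 21 splits can give, and adds no separate evidence. Beside LOY, the macrophage and tubular injury lists were themselves lower above number 10 (median -0.23 and -0.35, camera adjusted p = 0.00796 and 0.00363, 0.605 each with an estimated correlation). The antigen presentation list did not pass with number (median 0.07, camera adjusted p = 0.341). All the same, a structure by number remained possible and could add to the gene counts. The difference between low- and high-numbered LOY kidneys correlated with the deviation of Control animal 3 (r = 0.541, highest other Control 0.106). This is the only low-numbered Control kidney, so number cannot be told from a trait of that kidney. Each deviation was taken from the other Control kidneys, so these r are not independent. Set against podocyte and endothelium scores the macrophage score rose by 0.849 (exact permutation p = 0.00216), which argued against a lower tubule share alone. Without LOY animals 8 and 10 the macrophage score differed by 0.786. Its exact permutation p of 0.00476 of 210 splits was fixed in advance for the same reason.

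LOY animal 8 lay far from the other LOY kidneys across genes. Its deviation correlated with GC content (rho = 0.320, next kidney 0.241), as a GC bias would give. With transcript length rho was -0.298 (next -0.215), just short of the bound of 0.3 set for it, so length stays open. Without the 18 most abundant genes the SD of its deviation was 0.975 against 0.977 with them (highest other kidney 0.607). Leaving out so few of 14978 genes could hardly move an SD across genes in any kidney. This test therefore cannot decide whether a few genes taking most counts played a part. No biological explanation was tested.

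The B and plasma cell list was lower with ABT-263. Beyond the macrophage and T cell scores it differed by -0.344 (exact permutation p = 0.286 of 70 splits), so a loss of all leukocytes alike could not be excluded. In the LOY table the LOY kidneys numbered above 10 differed from the others by 0.0506 (SE 0.301) on this list, too imprecise to tell number from compound. The highest ABT-263 kidney lay below the lowest control-compound kidney by -0.423, so 1 kidney did not make the difference, although the adjusted p with an estimated correlation ran from 0.0450 to 0.184 when kidneys were left out. The compound may lower B cell transcripts, and the fully confounded animal numbers leave this untested.

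Other splits of the animals gave a measure of chance. The LOY gene count was reached in 1 of the 100 drawn splits, its own (176, highest other 0). That share is under 0.05, but most of the drawn splits do not part the animal numbers as LOY and Control do. The LOY list count was reached in 4 of 100 (26, highest other 29), and all 4 parted the low-numbered animals 4 to 1 as LOY and Control do. Of the 18 drawn splits of that kind 4 reached it, so chance was not excluded for the lists once number is respected; with number as a term 24 lists passed. For the genes 1 of those 18 reached 176, too few splits for a share under 0.05. For the ABT-263 genes the real count of 0 was bound to be reached in 35 of 35 splits, which tests nothing. The highest other count, 54, came from exchanging control-compound animal 6 with ABT263 animal 16. Every other kidney kept its group in that split, and without both kidneys the real grouping called 388 genes. The count of 54 therefore cannot tell a structure beside the compound from the compound or the animal number. Chance was not excluded for the ABT-263 lists (7 of 35; 17, highest other 24), the LOY genes in the ABT-263 table (6 of 35; median of 0.280 in size, highest other 0.453) or the correlation of the tables (5 of 35; -0.286, highest other 0.350 in size).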

How the results depend on the processing

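The animal-number term, the numbers above 10 alone, the pairs of kidneys left out and the left-out kidneys in the comparison of the tables were chosen only after the result was seen. No paired analysis was possible because the groups compared share no animal number. The LOY gene count of 176 was 825 with DESeq2, 1062 with voom, 105 with totals alone, 9 for changes over 1.2-fold and 549 at an adjusted p of 0.1. It ran from 0 to 607 with kidneys left out, was 0 in edgeR with animal number as a term (1194 at an unadjusted p under 0.05; median log2 fold change of the raised genes 0.91 against 1.06), 451 above number 10, 1121 without LOY animal 8 and Control animal 3, and 29 without LOY animals 8 and 10. Fewer kidneys lower power, which cannot account for the counts above 176 with kidneys left out. The cause was not tested otherwise. LOY lists went from 26 to 1 with an estimated correlation and to 19 with fry. ABT-263 genes went from 0 to 42 with DESeq2, 11 with voom, 0 to 9 with kidneys left out and 388 without control-compound animal 6 and ABT263 animal 16; lists went from 17 to 1 with an estimated correlation and 1 with fry. The LOY-higher genes in the ABT-263 table had a camera (limma) p of 0.146 with an estimated correlation. For the LOY-lower genes camera (limma) gave 0.0707 so, 0.00208 to 0.105 with kidneys left out, and 0.331 for the list without LOY animals 8 and 10, where only 3 genes were tested. The correlation of the tables ran from -0.350 to -0.201 with single kidneys left out and was -0.363 without control-compound animal 6 and ABT263 animal 16.

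With animal number as a term endothelium (adjusted p = 0.0327), oxidative phosphorylation (0.0894) and adipose tissue (0.0267) turned from higher to lower with LOY, as did oxidative phosphorylation above number 10 (4.28e-07). With ABT-263 the proximal tubule turned to higher without ABT263 animal 16 (0.0145; up to 0.936 with other kidneys left out). Without control-compound animal 6 and ABT263 animal 16, mitochondrially encoded (0.0117) and fatty acid oxidation genes (0.839) turned to higher; the cause was not tested. Counting a reversal only where a gene passed before or after it, of the 100 genes named with LOY 0 reversed in 2499 values (1844 kept their call, 558 weaker, 97 stronger). Of the 69 named with ABT-263 0 reversed in 1238 (1195 kept, 43 stronger). Genes that passed in neither fit did change sign, such as Havcr1 with ABT-263 (1.39; lowest -1.15) and Cd274 with LOY (0.11; lowest -0.11). At this depth 2-fold changes were recovered in 71.6% and 68.2% of simulated genes.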

Other observations

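The gene groups of this part and the tests of animal number were chosen only after the result was seen. Chemokine ligands, which recruit leukocytes, were higher in LOY kidneys in 26 of 27 cases, and 7 rose, among them Ccl9 (1.37 ± 0.21, SE) and Ccl2 (1.33 ± 0.28), with a median log2 fold change of 1.06 (camera p = 0.00771 with an estimated correlation). With ABT-263, 23 of 27 were lower (median -0.45, p = 3.42e-05; p = 0.0735 with an estimated correlation). Of 20 members of the inflammatory NF-kB pathway Nfkb2 (0.70), Nfkbie (0.81), Bcl3 (1.07) and Traf1 (1.26) rose with LOY (median 0.31, p = 3.37e-06; p = 0.0549 with an estimated correlation), and 12 of 20 were lower with ABT-263 (median -0.07; p = 0.383 with an estimated correlation). Solute carriers, a family of membrane transporters taken whole and not by tubule expression, were lower in 201 of 298 cases (67.4%, against 47.7% of all genes). Of them 2 passed the threshold (median -0.13, camera p = 2.89e-05, and p = 0.0661 with an estimated correlation). With ABT-263 their median was 0.02 (172 of 315 higher). Of the 176 genes that passed with LOY, 72 belonged to a fixed list and 104 to none.

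In the LOY table the division of animals at number 10 (5 up to 10, of which 4 LOY; 7 above) called 4150 genes by itself and 623 beside LOY. A division at 9 called 2870, and each of the 7 other divisions called 0 in edgeR. Acta2 (-1.02 ± 0.11) and the adipocyte gene Fabp4 (-1.79 ± 0.20) had the smallest p with number. With number the ribosomal protein list had a median of -0.65 (camera adjusted p = 2.83e-21; adjusted p = 0.508 with an estimated correlation), oxidative phosphorylation -0.52 (3.73e-10; 0.581) and adipose tissue -1.51 (0.000104; 0.508).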
